A study of Mus musculus with 6 samples.

How the data were processed

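LSK cells were sorted from the bone marrow of tamoxifen-treated WT mice and tamoxifen-inducible Ctcf conditional knockout mice, and total RNA was extracted with Trizol, labelled with biotin and hybridised to Affymetrix Mouse Gene 2.0 ST arrays, per the labels' protocols. The design text names CreER mice beside the conditional knockout, and the labels give the control genotype as WT, so whether the controls carried the recombinase is not settled by the sources used here. Each of the 6 arrays is labelled a biological replicate, 3 per group. The deposited values are log2 probe set summaries; RMA and the R package oligo are named, without versions, per the submitters' processing notes. RMA corrects background, normalizes arrays by quantiles and summarises probes, which compresses differences of dim probe sets and assumes like distributions on all arrays. The summary level, annotation release and genome build are not given in the sources used here.

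The value table held 41345 probe sets. GEO's platform annotation gave 1 gene symbol for 23521 of them, several for 1814 and none here for 16010; probe sets with several or none were left out of the gene table. Entrez identifiers of 23328 single-symbol probe sets were found in NCBI RefSeq's gene table of assembly GRCm38.p6, and 0 symbols changed. Each of the 22180 genes was represented by its probe set with the highest mean over the 6 arrays; 1082 genes had more than 1. No filter on low values was applied. A Gene ST probe set cannot separate near-identical copies, so values of gene families such as immunoglobulins and ribosomal proteins are uncertain.

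The knockout was compared with WT by limma 3.58.1 in R 4.3.3, with lmFit and eBayes at default settings on the deposited log2 values of all 6 arrays and the group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Differences are knockout minus WT, SEs come from the moderated fit, and SDs are between the 3 arrays of a group. For single values an exact two-sided permutation test of 3 against 3 was used, whose smallest p is 0.1. Gene lists, 36 in number, were fixed before the data were examined, and the 34 with at least 5 measured members were tested by camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The other alternatives planned were eBayes with trend and robust settings, array weights, only genes whose mean is above the median of all genes' means, a further quantile normalization, centring on the median of those brighter genes, the mean of a gene's probe sets, the replicate number as a block, each array left out in turn, all probe sets, a threshold of 0.1, an unadjusted p under 0.05 with at least 2-fold change, and lists without shared members. A model with a plasma cell score was added after the data were seen.

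The rule for named genes, also fixed before the data were examined, took Ctcf, then up to 12 genes per direction with the largest log2 differences among called genes whose groups did not overlap and whose brighter group lay above the median of all genes' means of 6.29, without symbols of predicted, small RNA, olfactory or receptor-segment form. It added up to 2 called members per direction of each list, the 3 brightest members in WT of each list of another cell type, and 18 genes named whatever their result, of which 3 are not analysed here. Further genes named in the text were chosen after their values were seen; these are list members given as examples, the genes of the closing section and the called genes that the rule leaves out.

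The test was checked on simulated data with 200 changed genes, in 20 runs over 22180 genes. These had the real genes' means, the shrunken spreads of the moderated fit and normal noise, independent between genes unless stated. Under these settings the test recovered 20.4% of genes changed by 0.5 on the log2 scale, 95.5% of those changed by 1 and 99.9% of those changed by 2, with 6.60% false calls. These shares do not give the recovery in the real data, whose noise and number of changed genes can differ. There 56 genes had an unadjusted p under 0.05 by limma with at least 2-fold change, and 13 of them were called. Camera with the preset correlation recovered 100% of lists shifted by 0.3 and called 1.36% of unshifted lists when genes varied independently. When the members of unshifted lists were given a correlation of 0.5, the preset test called 49.7% of the 34 lists and the test with an estimated correlation 0%. How many shifted lists the test with an estimated correlation or fry recovers was not simulated. A list that fails them is therefore not shown to be unshifted. As every group has 3 arrays, no search for outlying arrays was made.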

Results

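Gene expression was measured in LSK cells, the lineage-negative fraction of mouse bone marrow with Sca-1 on the surface and high c-Kit that holds the haematopoietic stem cells and the earliest multipotent progenitors. The arrays were 6 Affymetrix Mouse Gene 2.0 ST arrays, 3 of WT mice and 3 of mice with a tamoxifen-inducible deletion of Ctcf, which encodes the zinc finger protein CTCF that binds DNA at insulators and at the anchors of chromatin loops. The mice were 8 weeks old. They received 2 mg of tamoxifen a day for 3 days, and cells were sorted 24 hours after the last injection. Median log2 levels over all probe sets lay between 5.99 and 6.07 on the 6 arrays. Pearson correlations across genes, which are not independent replicates, were between 0.986 and 0.989 within groups and between 0.979 and 0.989 across groups. Precision is limited by the number of arrays.

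The single comparison of the design, knockout minus WT, asks what an acute loss of Ctcf does to the transcriptome of the compartment that maintains blood formation, with stem cell maintenance and quiescence as the subject of the study. Ctcf itself was at a log2 level of 8.56 ± 0.19 (SD, n = 3) in WT and 7.74 ± 0.14 (SD, n = 3) in the knockout. The log2 difference was -0.82 (SE 0.13), or 56.7% of the WT level, with all 3 knockout arrays below all 3 WT arrays. The exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 can give. With adjustment over all genes limma gave an adjusted p of 0.104, so the target gene missed the threshold of 0.05. The labels do not say which exons are deleted, and a probe set outside them would not follow the deletion.

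**Figure D1:**
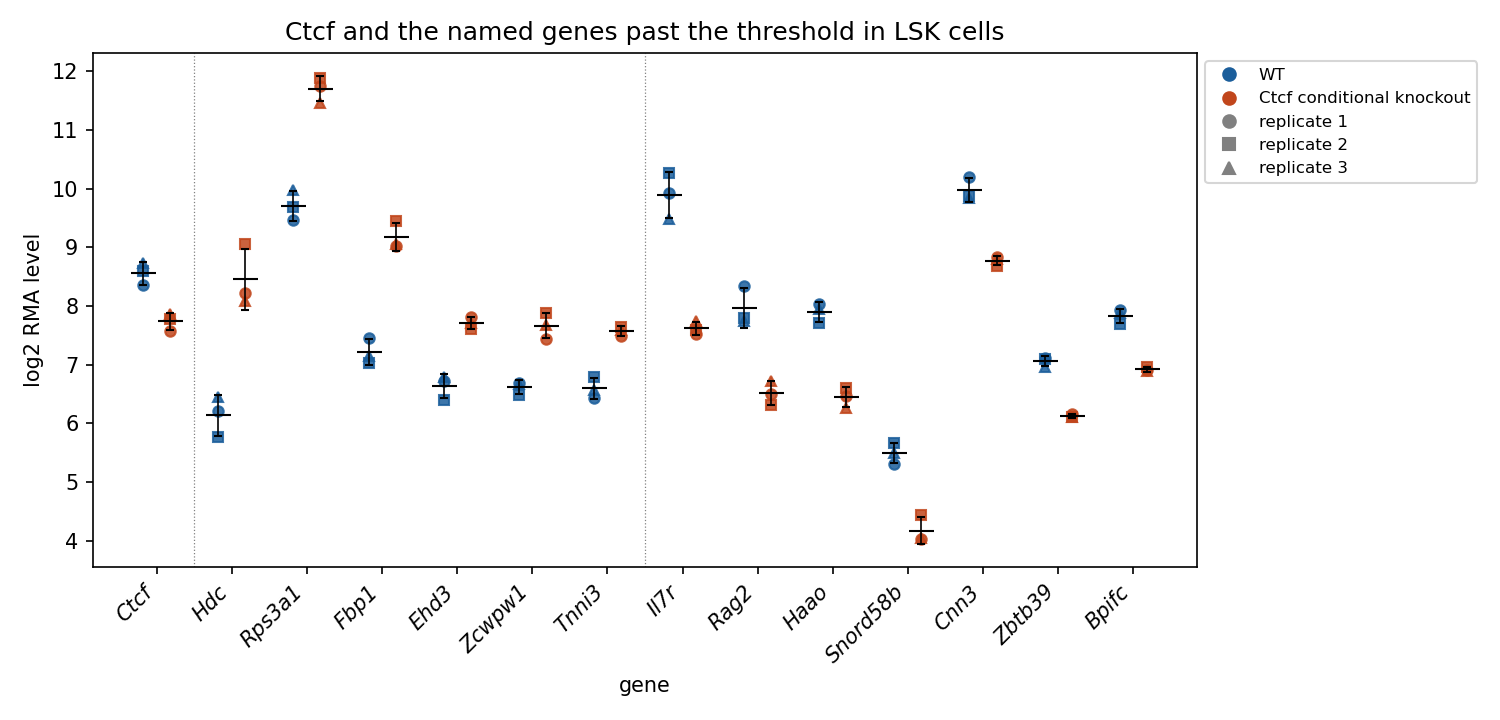
Log2 RMA level (y axis) of Ctcf and of the named genes past the threshold (x axis, italic), in order of Ctcf, genes higher in the knockout and genes lower in the knockout, split by dotted lines. Blue marks are WT arrays and red marks knockout arrays, the symbol gives the replicate, and the bar and whiskers give the mean and SD of 3 arrays; for every gene shown the 2 groups do not overlap.

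Few single genes passed the test, and the early lymphoid genes Il7r and Rag2 were among those that fell. Il7r, the interleukin-7 receptor chain that marks lymphoid progenitors, fell by 2.28 on the log2 scale (SE 0.18, adjusted p = 0.00672), from 9.90 ± 0.39 to 7.62 ± 0.11 (SD, n = 3 each). Rag2, a subunit of the recombinase that assembles antigen receptor genes, fell by 1.45 (adjusted p = 0.0455). Fbp1, the fructose bisphosphatase of gluconeogenesis, rose 3.90-fold (log2 1.96, SE 0.16, adjusted p = 0.00672), and Hdc, the enzyme that makes histamine, rose 4.98-fold (log2 2.32, SE 0.26, adjusted p = 0.0309). With 1 array left out at a time, Hdc passed in 1 of 6 fits and Rag2 in 0. By limma with Benjamini-Hochberg adjustment 16 of 22180 genes changed, 6 higher and 10 lower, and 13 of them by at least 2-fold, 5 higher and 8 lower.

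The other genes higher in the knockout were Rps3a1, a ribosomal protein gene (log2 1.99, adjusted p = 0.00672), Ehd3, an endocytic recycling factor (log2 1.07, adjusted p = 0.0437), Zcwpw1, a histone reader of meiotic recombination (log2 1.05, adjusted p = 0.0489), and Tnni3, which encodes cardiac troponin I (log2 0.98, adjusted p = 0.0455). The rise of Rps3a1 rests on its brighter probe set, at 9.71 ± 0.25 in WT and 11.70 ± 0.21 in the knockout. A dimmer probe set assigned to Rps3a1 differed by 0.06 (SE 0.16), and the mean of both by 1.02, so the gene's value is uncertain. The number of the dimmer one, 17406440, is close to that of Mnd1, 17406323, a neighbour of Rps3a1 in gene order. That of the brighter one, 17289787, is not. Whether the rise is that of Rps3a1 or of a near-identical copy elsewhere is not settled. Among the genes that fell were Haao, an enzyme of tryptophan breakdown (log2 -1.45, adjusted p = 0.0117), Cnn3, an actin-binding calponin (log2 -1.20, adjusted p = 0.0269), Zbtb39, a zinc finger protein gene (log2 -0.93, adjusted p = 0.0269), Bpifc (log2 -0.91, adjusted p = 0.0347) and the small nucleolar RNA Snord58b (log2 -1.32, adjusted p = 0.0285). The remaining 3 of the 10, given here after their values were seen, were a variable segment of the immunoglobulin heavy chain (log2 -2.59, adjusted p = 0.00871), the pseudogene Gm6548 (log2 -1.07, adjusted p = 0.0269) and the non-coding RNA Gm5914, which adjoins Ctcf in gene order (log2 -1.13, adjusted p = 0.0459). All 16 kept their direction when any array was left out, which had to follow because the groups of all 16 do not overlap. The count fell to 4 without WT replicate 1, 5 without WT replicate 2 and 8 without WT replicate 3. It fell to 7 without knockout replicate 2, 4 without knockout replicate 3 and 0 without knockout replicate 1. In the last of these fits limma had 1725 genes at an unadjusted p under 0.05. Fbp1, Il7r and Rps3a1 passed in 5 of these 6 fits, the heavy chain segment in 4, Haao in 2, and Hdc and Snord58b in 1 each. The other 9, which are Rag2, Ehd3, Zcwpw1, Tnni3, Cnn3, Zbtb39, Bpifc, Gm6548 and Gm5914, passed in 0 of them.

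At an unadjusted p under 0.05 there were 1799 genes, 1115 higher and 684 lower, where chance gives 1109 in all on average. The spread around that average widens when genes vary together. The 9 other splits of the 6 arrays into 3 and 3 gave between 473 and 1621, and 4 of them more than 1109. Among those changed at least 2-fold the balance was the opposite, 18 higher and 38 lower. The groups did not overlap for 13.3% of genes, where chance gives 10%.

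No measured gene of stem cell identity passed the test. All 36 missed it, over all genes or adjusted over the list alone, and 17 had a positive and 19 a negative difference, with a median of -0.01 (camera adjusted p = 0.829). As only 16 of 22180 genes passed in all, the lack of a call among 36 says little about them. At an unadjusted p under 0.05 by limma 4 of the 36 were higher and 0 lower, against 1115 higher and 684 lower among all genes. Kit differed by -0.22, Cd34 by -0.02, Procr by -0.03 and Slamf1 by 0.33, each with a limma adjusted p of 0.532 or more. Kit moved between -0.30 and -0.09 with 1 array left out. Cells were sorted for high c-Kit, so the sort itself may hold the level of Kit. The 29 genes of quiescence and CDK inhibition had a median of 0.00 (camera adjusted p = 0.703), and none passed adjusted over the list alone. Within this list Cdkn1a, a CDK inhibitor of the DNA damage response, differed by 0.73 (SE 0.18, limma adjusted p = 0.341) with groups that did not overlap. Over its alternatives Cdkn1a lay between 0.40 and 0.90. By contrast Cdkn1b differed by 0.06, Cdkn1c by 0.15 (between 0.02 and 0.24 with 1 array left out) and Cdkn2a by 0.03. The 28 p53 targets had a median of 0.09 (camera adjusted p = 0.317) and the 21 apoptosis regulators a median of -0.01 (camera adjusted p = 0.958), with none passing over either list alone. Cxcr4, the receptor that holds stem cells in the marrow, differed by 0.25 (limma adjusted p = 0.590), and the 27 genes of niche adhesion and homing had a median of 0.07 (camera adjusted p = 0.663); Selp and Cd9 passed adjusted over the list alone, both higher. With 1 array left out the p53 target median moved between 0.05 and 0.11 and the niche median between 0.03 and 0.08.

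By camera with its preset correlation, cell cycle genes were higher in the knockout as a set, with a large spread between arrays. All 28 measured G2/M genes had a positive difference, with a median of 0.54, and so did all 27 S phase genes, with a median of 0.32. The preset correlation of 0.01 gave adjusted p = 2.95e-12 and adjusted p = 7.01e-10. Both were lost with an estimated correlation (adjusted p = 0.491 for each). No member passed, over all genes or adjusted over the list alone. Mki67, the proliferation antigen, differed by 0.63 (SE 0.21), Cdk1 by 0.66 (SE 0.28) and Ccna2 by 0.76 (SE 0.26). With 1 array left out they moved between 0.42 and 0.85, between 0.32 and 0.94 and between 0.45 and 0.95. WT replicate 2 had the lowest G2/M median, -0.53 against 0.09 and 0.47 on the other WT arrays, and without it the G2/M difference was 0.27 and the S phase difference 0.19. The array medians of the groups overlapped for both lists (exact two-sided permutation p = 0.2 for each). WT replicate 3 lay above knockout replicate 3 for G2/M, 0.47 against 0.28, and above knockout replicate 1 for S phase, 0.29 against 0.26. The 26 replication-dependent histone genes had a median of 0.32 (camera adjusted p = 0.000922, and adjusted p = 0.491 with an estimated correlation), which became 0.11 without WT replicate 2 (adjusted p = 0.0569) and 0.17 without knockout replicate 1 (adjusted p = 0.164). Oxidative phosphorylation genes were positive for 25 of 26 members (median 0.25, camera adjusted p = 1.46e-06, and adjusted p = 0.491 with an estimated correlation), as were 22 of 28 antioxidant genes (median 0.19, camera adjusted p = 0.000965, and adjusted p = 0.491 with an estimated correlation). No member of these 3 lists passed adjusted over the list alone. Without WT replicate 2 the oxidative phosphorylation median was 0.14 and the antioxidant median 0.11. The 20 DNA damage response genes had a median of 0.11 (camera adjusted p = 0.00779, and adjusted p = 0.491 with an estimated correlation), which did not pass without WT replicate 1 (median 0.08, adjusted p = 0.145) or without knockout replicate 2 (median 0.07, adjusted p = 0.205) and was 0.18 without knockout replicate 1, and none of them passed over the list alone.

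**Figure D2:**
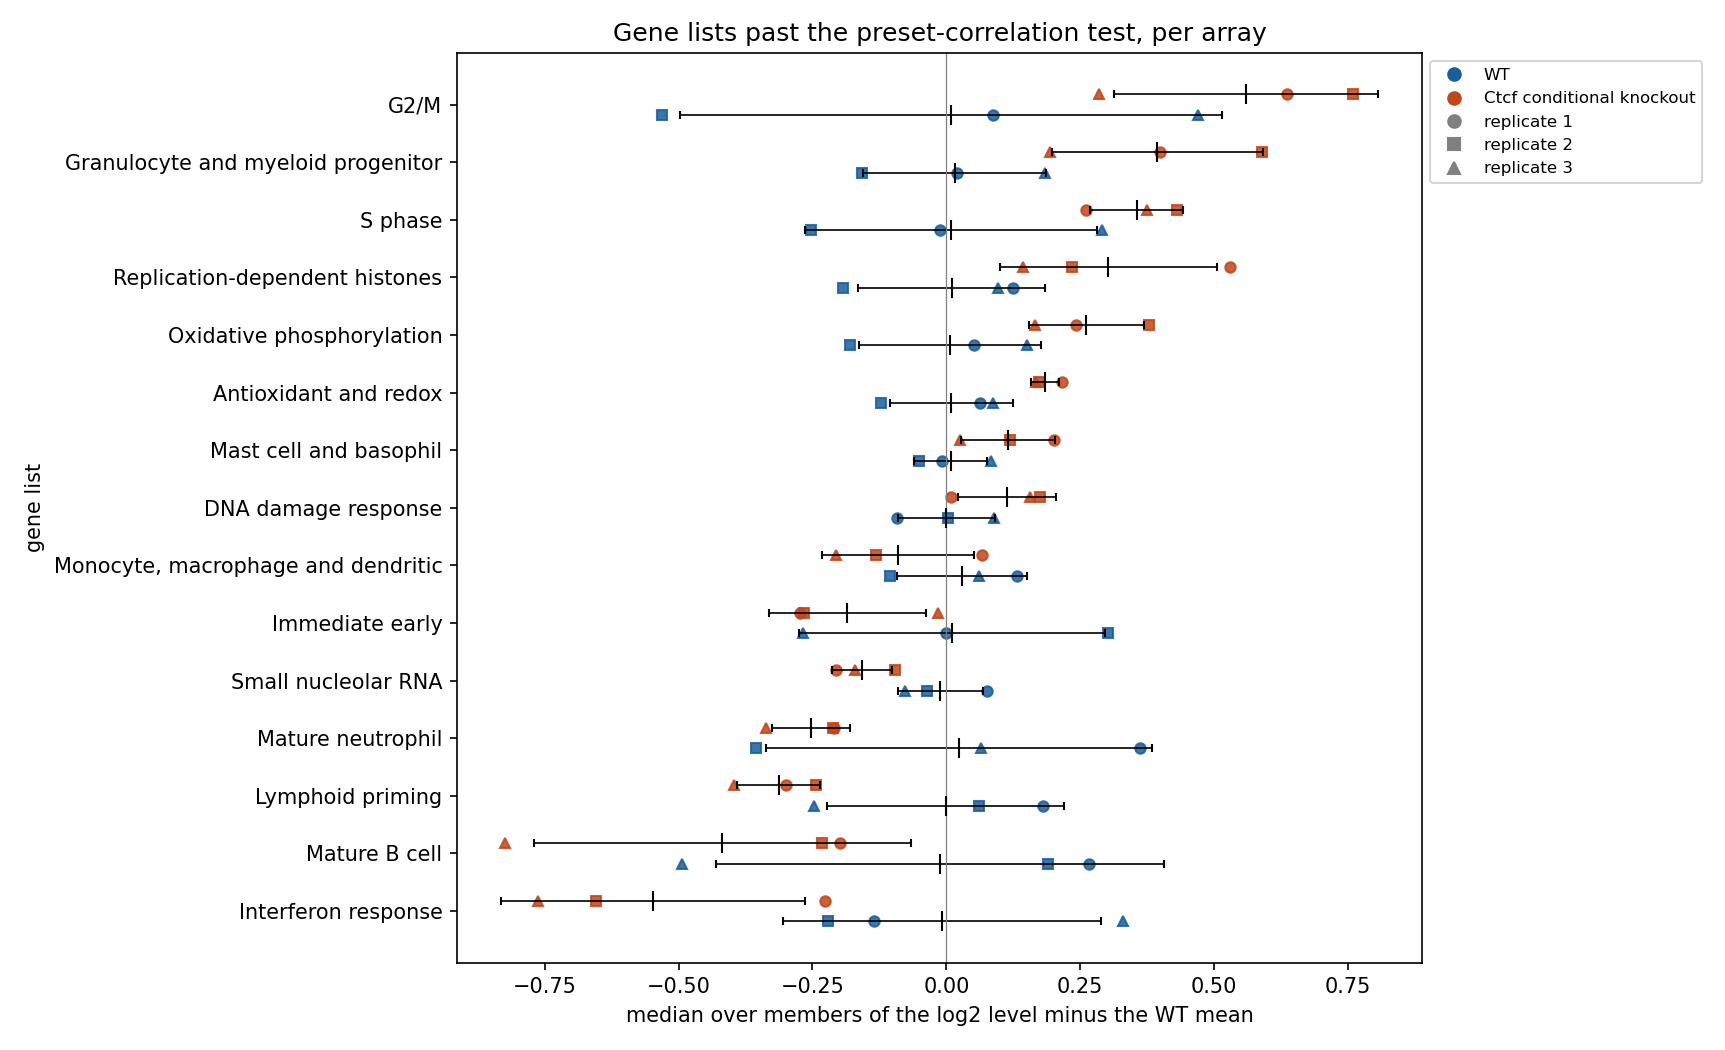
Median over each list's measured members of the log2 level minus the WT mean of the gene (x axis), for the 15 gene lists past camera with its preset correlation (y axis). Blue marks are WT arrays and red marks knockout arrays, the symbol gives the replicate, and the bar and whiskers give the mean and SD of 3 arrays. The arrays of the 2 groups stand apart for 6 of the 15 lists, mostly by little. The nearest arrays of WT and knockout are at -0.221 and -0.227 for interferon response and 0.184 and 0.194 for myeloid progenitor genes. The widest gap is that of antioxidant genes, 0.087 and 0.167. WT replicate 2 is the lowest G2/M array.

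Genes of granulocyte and myeloid progenitors were higher in the knockout by the same test. Their median over 26 genes was 0.50 (camera adjusted p = 1.24e-08, and adjusted p = 0.491 with an estimated correlation), 9 passed adjusted over the list alone, all higher, and none passed over all genes. Elane, neutrophil elastase, differed by 1.21 (SE 0.19, limma adjusted p = 0.104), Mpo, myeloperoxidase, by 0.85 (SE 0.18, limma adjusted p = 0.220), Ctsg by 1.15 (SE 0.26) and Ms4a3 by 1.40 (SE 0.33). Among 21 mast cell and basophil genes Hdc passed over all genes and Mcpt8, a basophil protease (log2 1.11, limma adjusted p = 0.0708), passed only over the list alone; the list median was 0.14 (camera adjusted p = 0.0214, and adjusted p = 0.491 with an estimated correlation). The mast cell and basophil call was lost without WT replicate 2 (adjusted p = 0.0510) and without knockout replicate 1 (adjusted p = 0.134). Its median was 0.34 among the brighter genes, 0.09 with centring on them and 0.06 with a score of plasma cell genes in the model, which was added after the data were seen.

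Lymphoid genes were lower by the same test. Of 29 lymphoid priming genes 26 had a negative difference, with a median of -0.36 (camera adjusted p = 6.52e-09, and adjusted p = 0.491 with an estimated correlation). Il7r and Rag2 passed over all genes, while Ccr7, a chemokine receptor, passed adjusted over the list alone in the other direction (log2 0.56). Flt3, the receptor kinase of multipotent and lymphoid progenitors, differed by -0.42 (SE 0.16) and Dntt by -0.57 (SE 0.19, between -0.68 and -0.36 with 1 array left out). All 17 measured genes of the mature B cell list had a negative difference, with a median of -0.48 (camera adjusted p = 2.28e-06, and adjusted p = 0.491 with an estimated correlation), and none passed over the list alone. Transcripts of antibody-secreting cells had a bright signal: Ighm stood at 13.85 ± 0.27 in WT and 13.21 ± 0.41 in the knockout, and Jchain at 12.50 ± 0.59 and 11.61 ± 0.69 (SD, n = 3 each). With the mean of its probe sets the Ighm difference moved from -0.64 to -1.27. With 1 array left out it moved between -0.83 and -0.43, and that of Jchain, at -0.90, between -1.23 and -0.50. Over all alternatives the smallest falls were -0.22 for Ighm and -0.05 for Jchain. The array medians of the B cell list were lowest in replicate 3 of both groups, at -0.49 in WT and -0.82 in the knockout. Leaving out WT replicate 1, WT replicate 3 or knockout replicate 3 moved the B cell median to -0.25, -0.80 or -0.22, and leaving out WT replicate 1 moved the lymphoid priming median to -0.20. With an array score of plasma cell genes in the model, an alternative added after the data were seen, the B cell median was -0.03, the lymphoid priming median -0.09, and no gene passed by limma, with 924 at an unadjusted p under 0.05.

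Interferon response genes were lower by camera with the preset correlation. Of 29 measured genes 25 had a negative difference, with a median of -0.52 (camera adjusted p = 5.14e-15, and adjusted p = 0.491 with an estimated correlation). Over the list alone 14 passed, all lower, and none over all genes. The list's array median of knockout replicate 1, at -0.227, was close to that of WT replicate 2, at -0.221. Oas2, a double-stranded RNA sensor, differed by -1.16 (SE 0.23), the antiviral gene Rsad2 by -1.20 (SE 0.26) and Irf7, a transcription factor of the interferon pathway, by -1.03 (SE 0.32, between -1.28 and -0.64 with 1 array left out). Small nucleolar RNAs were negative for 61 of 73 genes (median -0.20, camera adjusted p = 3.04e-09, and adjusted p = 0.491 with an estimated correlation), with Snord58b past the threshold. Mature neutrophil genes had a median of -0.26 (camera adjusted p = 0.000776, and adjusted p = 0.491 with an estimated correlation), with a limma adjusted p of 0.241 for Ngp, a neutrophil granule protein, at -2.44 (SE 0.52); without WT replicate 1 the list's median was -0.13 (adjusted p = 0.0589). In this list 1 gene passed lower and 1 higher over the list alone, Ngp and Stfa2. Immediate early genes had a median of -0.13 (camera adjusted p = 0.00458, and adjusted p = 0.522 with an estimated correlation), which became 0.00 without WT replicate 2 (adjusted p = 0.641) and -0.07 without knockout replicate 1 (adjusted p = 0.0705), -0.22 without WT replicate 3 and -0.30 without knockout replicate 3; Myc differed by -0.50 (SE 0.15). Monocyte, macrophage and dendritic genes had a median of -0.09 (camera adjusted p = 0.0214, and adjusted p = 0.502 with an estimated correlation), lost without WT replicate 1 (median -0.04, adjusted p = 0.210), WT replicate 3 (median -0.10, adjusted p = 0.155) or knockout replicate 3 (median -0.04, adjusted p = 0.511), and -0.18 without WT replicate 2 or knockout replicate 1.

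Signals of markers of other cell types carry no detection call, so they show neither presence nor relative abundance. The 3 per list with the brightest WT signal, with the difference in brackets, were Lyz2 at 10.33 (-0.27) and S100a8 at 8.85 (-0.52) beside Ngp among neutrophil genes. Beside Flt3 among monocyte and dendritic genes were Cst3 at 10.22 (0.10) and Ly86 at 9.88 (0.20). Ly6c2 at 12.08 (-0.02) and Calr at 11.72 (0.31) stood beside Elane among myeloid progenitor genes. Wfdc17 stood at 11.60 (-0.58) beside Flt3 and Dntt among lymphoid genes, and Xbp1 at 10.43 (-0.51) beside Ighm and Jchain among B cell genes. Erythroid genes had Car2 at 11.18 (0.33), Car1 at 8.95 (0.56) and Cd59a at 8.66 (0.44). Megakaryocyte genes had Rap1b at 10.91 (0.29), Fli1 at 10.12 (0.11) and Cpne2 at 9.66 (0.27). For T and NK cells they were Nkg7 at 10.24 (0.68), Lat at 8.53 (0.12) and Ccl5 at 8.29 (-0.37). For mast cells and basophils they were Srgn at 12.04 (0.00), Ccl3 at 10.69 (-0.85) and Cpa3 at 9.42 (0.45), and for endothelial and stromal cells Eng at 10.10 (-0.02), Igfbp4 at 9.30 (0.25) and Pdgfrb at 7.90 (0.37). None of these passed limma's test over all genes. With 1 array left out S100a8 moved between -1.07 and -0.08, Lyz2 between -0.58 and -0.03, and Wfdc17 between -0.87 and -0.20. Ccl3 moved between -1.34 and -0.45, Ccl5 between -0.50 and -0.16, Cpa3 between 0.18 and 0.73, Calr between 0.15 and 0.47, Cpne2 between 0.14 and 0.35 and Pdgfrb between 0.25 and 0.48.

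In all, camera with the preset correlation placed 15 of 34 tested lists past the threshold, 8 higher and 7 lower. With an estimated correlation none passed, with 2 lists at an unadjusted p under 0.05, and by fry none passed, with 3 at an unadjusted p under 0.05. The other lists did not pass this test. Megakaryocyte and platelet genes had a median of 0.13 (camera adjusted p = 0.0685), with 4 genes higher and 3 lower over the list alone, among them Itgb3 at 0.75 and Thbs1 at -1.10. Over their alternatives Itgb3 lay between 0.61 and 0.84 and Thbs1 between -1.42 and -0.63. In the MHC class II list (median 0.17, camera adjusted p = 0.198) H2-DMb2 differed by 1.07 and H2-Ob by -0.82, both past the threshold over the list alone. Erythroid genes had a median of 0.06 with camera pointing lower (adjusted p = 0.930), and higher with centring on the brighter genes, and Gata1 differed by 0.12. Medians were 0.06 for chromatin architecture genes (camera adjusted p = 0.0906), 0.13 for glycolysis and hypoxia (adjusted p = 0.0906), 0.03 for MYC and ribosome biogenesis (adjusted p = 0.784), 0.02 for cytosolic ribosomal proteins (adjusted p = 0.705) and 0.03 for heat shock and unfolded protein genes (adjusted p = 0.784), where Asns passed over the list alone. They were -0.07 for T and NK cell genes (adjusted p = 0.0899), 0.05 for endothelial and stromal genes (adjusted p = 0.618), -0.09 for NF-kB inflammation (adjusted p = 0.198), 0.01 for imprinted genes (adjusted p = 0.958), -0.02 for Hox genes (adjusted p = 0.340) and -0.04 for clustered protocadherins (adjusted p = 0.206). Some of these passed under an alternative with all 6 arrays: chromatin architecture and T and NK cell genes with array weights, megakaryocyte genes with centring on the brighter genes, and megakaryocyte and MHC class II genes with the plasma cell score. Others passed when 1 array was left out. Without WT replicate 1 these were megakaryocyte genes (median 0.18, adjusted p = 0.0345). Without WT replicate 2 they were chromatin architecture (median 0.10, adjusted p = 0.0193) and T and NK cell genes (median -0.04, adjusted p = 0.0238). Without knockout replicate 1 they were chromatin architecture (median 0.14, adjusted p = 0.00827), MYC and ribosome biogenesis (median 0.12, adjusted p = 0.0390), glycolysis and hypoxia (median 0.14, adjusted p = 0.0249) and T and NK cell genes (median -0.06, adjusted p = 0.0390). Without knockout replicate 3 they were MHC class II (median 0.36, adjusted p = 0.0327), megakaryocyte genes (median 0.19, adjusted p = 0.00266) and clustered protocadherins (median -0.10, adjusted p = 0.0416). The chromatin architecture median was 0.01 without WT replicate 1. A list of mitochondrially encoded genes had 0 measured members.

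The labels give all 6 mice as male. Xist, the RNA that coats the inactive X chromosome of females, was at 12.85 ± 0.21 in WT and 12.79 ± 0.22 in the knockout (SD, n = 3 each), above 99.8% of genes on each array, while the Y-linked genes Kdm5d, Uty and Eif2s3y lay between 2.89 and 4.57 on all arrays. Of these 4 genes 0 passed the threshold by limma and 0 had an unadjusted p under 0.05 between the groups.

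**Figure D3:**
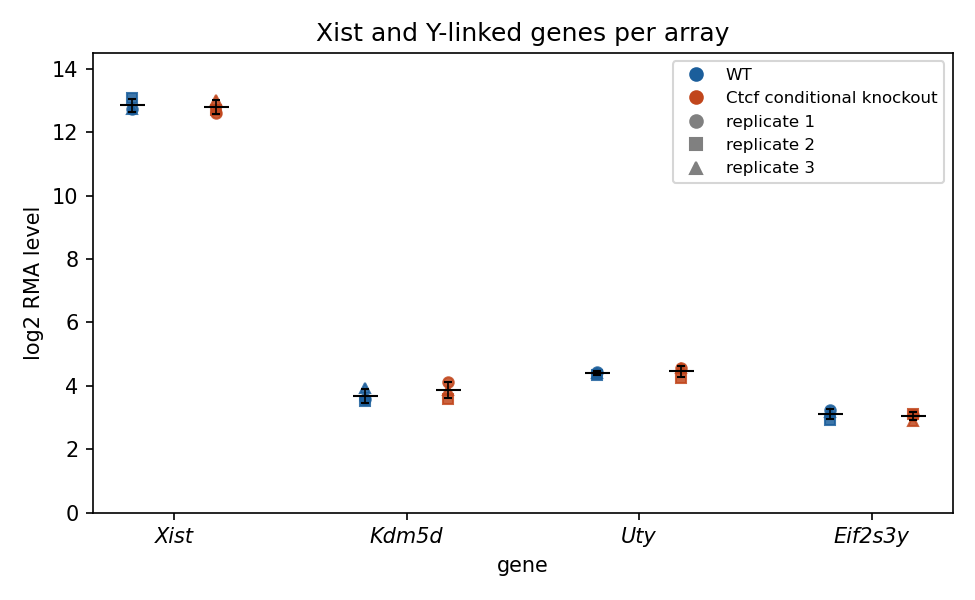
Log2 RMA level (y axis, from 0) of Xist and of the Y-linked genes Kdm5d, Uty and Eif2s3y (x axis) on each array. Blue marks are WT arrays and red marks knockout arrays, the symbol gives the replicate, and the bar and whiskers give the mean and SD of 3 arrays; Xist lies between 12.61 and 13.08 on all arrays and the Y-linked genes at 4.57 or below.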

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

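No test in this part was chosen after its result was seen. A fit of all probe sets covered 17824 that have several gene symbols or none here and enter no gene or list result of the report. Among these 3 passed an adjusted p under 0.05 by limma, 0 higher and 3 lower in the knockout, all without a gene name here; they are the 3 that pass over all probe sets in the part below. Probe set 17284420 differed by -6.85 on the log2 scale (adjusted p = 0.00460), from between 11.4 and 12.3 on the WT arrays to between 4.38 and 5.20 on the knockout arrays. Probe set 17284617 differed by -6.07 (adjusted p = 0.0217), from between 8.86 and 10.3 to between 3.47 and 3.95. The other differed by -2.97 (adjusted p = 0.0217), from between 9.19 and 9.66 to between 6.20 and 6.75. In size these 3 differences exceed those of all 16 called genes, and no explanation for them was tested. The numbers of the first 2 lie near those of Ighm, 17284360, and of the called heavy chain segment, 17284577. Whether they measure the immunoglobulin heavy chain locus was not tested, and they are not among the immunoglobulin genes counted below.

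The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. For each count that follows, 1 of the 10 splits, the real one, gave a result as large. The real split called 16 genes where the highest other split called 0. It called 13 genes changed at least 2-fold against a highest other of 0, and 6 higher and 10 lower genes against a highest other of 0 on either side. For gene lists past camera with the preset correlation the real split gave 15 and the highest other split 13.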

How the results depend on the processing

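The model with a plasma cell score was chosen after the data were seen; the other alternatives were planned. Ctcf stayed lower and short of the threshold in all 14 alternatives, between -0.996 and -0.735, with adjusted p from 0.0574 to 0.438. The 16 calls, 6 higher and 10 lower with 13 at least 2-fold, were all kept with trend and robust settings, which gave 25 genes, 11 of them higher, and 15 of the 15 tested were kept among the brighter genes, with 10 higher. All 16 were also kept with array weights, a further quantile normalization, centring on the brighter genes and the mean of probe sets, which moved Rps3a1 from 1.99 to 1.02 and, among named genes not called, Ighm from -0.64 to -1.27 and Rap1b from 0.29 to 0.13. An adjusted p under 0.1 gave 26 genes with 11 higher, and an unadjusted p under 0.05 with at least 2-fold change gave 56, 18 higher and 38 lower. Leaving out 1 array left 0 to 8 genes, 0 to 3 higher, 0 to 5 lower and 0 to 8 at least 2-fold, in fits with fewer arrays; 0 is without knockout replicate 1, where limma had 1725 at an unadjusted p under 0.05. Over all probe sets 3 passed, 0 higher and 3 lower, all 3 at least 2-fold, and 0 of the 16 calls were kept; that fit holds more tests and noisier probe sets, with a prior SD of 0.181 on 2.79 degrees of freedom against 0.159 on 4.66. With the plasma cell score 0 genes passed by limma, 0 higher, 0 lower and 0 at least 2-fold, with 924 at an unadjusted p under 0.05; this fit estimates a further term from 6 arrays. Whether the replicate numbers pair the arrays stays open, as the labels do not say if equal numbers share a litter or day. The correlations of deviations for replicates 1, 2 and 3 were 0.29, 0.016 and -0.14, so 1 of 3 same-numbered pairs was over 0.1. Of the 6 arrays 2 correlated best with their own number. The plasma cell score was lowest in replicate 3 of both groups. With the replicate block 7 genes passed, 2 higher and 5 lower, all 7 at least 2-fold, and 5 of the 16 calls and all 15 list calls were kept; the block leaves fewer residual degrees of freedom.

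The 15 list calls became 0 with camera's estimated correlation and 0 with fry, with 2 and 3 lists at an unadjusted p under 0.05. On simulated data the preset test called 49.7% of unshifted lists whose members had a correlation of 0.5. Recovery of shifted lists was simulated for the preset test only, so these losses do not show that the lists are unshifted. Otherwise 12 to 17 lists passed, 13 to 17 when 1 array was left out. With the plasma cell score 10 of the 15 calls were kept: those of DNA damage response (median 0.079), mature neutrophil (-0.20), monocyte (-0.034) and immediate early genes (-0.056) were lost and 1 turned, while MHC class II (0.32) and megakaryocyte genes (0.24) passed. Array weights lost the immediate early call (-0.035) and added chromatin architecture (0.10) and T and NK cell genes (-0.066). Among list calls that were kept, medians moved by over 1.5 times for mast cell and basophil genes (from 0.14 to 0.34 among the brighter genes, 0.088 with centring and 0.060 with the plasma cell score), DNA damage response (0.11 to 0.057) and monocyte genes (-0.090 to -0.15) with centring, and S phase (0.32 to 0.19) and lymphoid priming (-0.36 to -0.089) with the plasma cell score. The brighter genes alone lost the monocyte call (-0.11), and centring added megakaryocyte genes (0.078). The direction of the list test turned in 34 cases and the sign of a named gene in 25, all with an adjusted p of 0.163 or more, and the cause was not tested. List medians near 0 also changed sign while the test kept its direction: with centring those of quiescence (-0.051), MYC (-0.030), endothelial (-0.0046), heat shock (-0.027), imprinted (-0.041) and ribosomal protein genes (-0.035), with a further quantile normalization that of Hox genes (0.0087), and others under further alternatives. With the plasma cell score the mature B cell test turned (median -0.031, adjusted p = 0.857, over its alternatives 8.46e-13 to 0.857), as did HSC identity (0.038), MYC and ribosome biogenesis (-0.075) and Ly6c2 (0.43). Among the brighter genes the tests turned for quiescence (median 0.0021), apoptosis (-0.016), MYC (0.026), niche adhesion (0.064), erythroid genes (0.14) and ribosomal proteins (0.020). Apoptosis also turned with a further quantile normalization (-0.0091) and with the mean of probe sets (-0.0072), erythroid genes with centring (0.0067) and fry (0.063), HSC identity with fry (-0.011) and imprinted genes without shared members (0.010). Single genes turned for Cd34 with array weights (0.0039), Cdkn2a with centring (-0.030), and Eng (0.0070) and Srgn (0.0023) with a further quantile normalization. Leaving out 1 array moved Car1 between -0.40 and 1.34, Cd34 between -0.066 and 0.059, Cdkn1b between -0.060 and 0.30, Cdkn2a between -0.020 and 0.049, Cst3 between -0.021 and 0.25, Eng between -0.076 and 0.056, Fli1 between -0.022 and 0.20, Gata1 between -0.083 and 0.26, Lat between -0.013 and 0.26, Ly6c2 between -0.24 and 0.36, Ly86 between -0.043 and 0.37, Procr between -0.079 and 0.045, and Srgn between -0.032 and 0.040. List medians moved between -0.059 and 0.030 for HSC identity, -0.030 and 0.048 for quiescence, -0.022 and 0.030 for apoptosis, -0.049 and 0.12 for MYC, -0.079 and 0.36 for MHC class II, -0.065 and 0.18 for erythroid genes, -0.072 and 0.10 for heat shock, -0.046 and 0.092 for imprinted genes, and 0.0021 and 0.051 for ribosomal proteins. They moved between 0.063 and 0.18 for glycolysis, -0.077 and -0.016 for T and NK cell genes, -0.019 and 0.086 for endothelial genes, -0.13 and -0.014 for NF-kB inflammation, -0.057 and 0.018 for Hox genes and -0.10 and -0.014 for protocadherins. Of the 1296 alternatives of named genes beside Ctcf 1150 kept direction and side, 100 lost a call and 21 gained one, and of 577 for lists, by the direction of the test, these were 480, 48 and 15. Only a called gene or list can lose a call, and most of the 93 named genes were not called. The share kept is therefore no measure of how stable the calls are. Rag2, Cnn3 and Zcwpw1 each lost their call in 8 of 14 alternatives, and Fbp1, Il7r and Rps3a1 each in 2 of 14. No background level is given with the values, so dim genes such as Snord58b, at 5.49 in WT and 4.17 in the knockout, have no detection call.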

Other observations

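The tests of Xist and the Y-linked genes, the test of chance positions in gene order and the model with a plasma cell score were chosen after the values they concern were seen. Genes singled out here were also chosen after their values were seen.

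At an adjusted p under 0.1 limma called 26 genes. Those added included Mcpt8 (log2 1.11, adjusted p = 0.0708), Mnd1 (log2 1.91, adjusted p = 0.0708), Nxpe5 (log2 1.11, adjusted p = 0.0742) and Dmc1 (log2 0.74, adjusted p = 0.0896) on the higher side, and the receptor gene Tlr6 (log2 -1.02, adjusted p = 0.0618) and the transporter gene Slc35d3 (log2 -1.43, adjusted p = 0.0649) on the lower side.

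Zcwpw1, Mnd1 and Dmc1 act in meiotic recombination, which raises the hypothesis that germline genes rise in the knockout. It was tested on 43 other measured meiotic and germline genes. Their median was -0.01, with quartiles of -0.10 and 0.14, against 0.74 for the smallest rise of the 3 genes. Of the 43 genes 20 were positive, and 3 were higher and 2 lower at an unadjusted p under 0.05. Camera over these genes (n = 43) pointed lower with p = 0.598, and with p = 0.720 under an estimated correlation. Ddx4, a germline helicase gene, was at -0.85 (adjusted p = 0.184). These values argue against a broad rise of germline genes, and why the 3 genes were higher was not tested.

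The male labels disagree with the sex-linked genes. Xist stood at or above the 99.85th percentile of genes on each array, and Kdm5d, Uty and Eif2s3y at or below the 13.44th, which is consistent with RNA of female mice. Among all 17 Y-linked genes with a value the highest percentile on any array was 60.95 and the median level 4.33. Y-linked probe sets that do not respond could account for the dim Y-linked genes, which was not tested, but not for Xist, which lay at least 6.30 log2 units above the median of genes on every array. Both groups show the pattern, so it does not follow genotype, and whether the label or the mice are in error was not tested.

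Immunoglobulin transcripts were bright in cells sorted as lineage-negative. Of 20 segments and constant genes 19 were lower in the knockout, with a median difference of -1.32 and a median WT level of 11.4, and 8 had an unadjusted p under 0.05. A candidate source is plasma cells carried over in varying amounts, which the lineage-negative and high c-Kit gates would remove. An array score of Jchain, Mzb1, Tnfrsf17, Pou2af1 and Xbp1, of which the mature B cell list holds 4, was set against 13 further plasma cell genes, of which other lists hold 0. How many of them LSK cells express themselves was not tested. Among transcripts that such cells make in bulk, Ighm stood at 13.8 and Jchain at 12.5 in WT, and the brightest of the 20 immunoglobulin genes at 13.77; levels of different probe sets do not rank abundance.

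Over the 13 genes the median correlation of deviations from the group means with the score was 0.83, from 0.33 to 0.98, against -0.05 over all genes, and 0 of 10000 random gene sets reached it. For their mean, Pearson r was 0.93 (exact permutation p = 0.0833 within groups, where the smallest possible is 0.0278) and Spearman rho 0.71 (exact permutation p = 0.222). Without replicate 3 of both groups, the arrays farthest from the median, r was -0.47, so the relation rests on these 2 arrays. Of the 13 genes 12 were lower in the knockout, 3 of them at an unadjusted p under 0.05. Whether the knockout sort held fewer such cells stays open.

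The falls of Il7r and Rag2 did not follow the array score of plasma cell genes. Neither gene is in the score and both are early lymphoid genes, so the score could hardly have taken up their falls. The model therefore does not decide whether carried-over cells account for these falls. Within groups the score varied mostly through replicate 3, at -0.84 from the group mean in WT and -0.73 in the knockout. A change in other B lineage cells is not covered by the score and was not tested. With the score in the model Il7r kept 92.3% of its difference, from -2.28 (SE 0.18) to -2.10 (SE 0.24), and Rag2 97.2%, from -1.45 (SE 0.18) to -1.41 (SE 0.25). Both calls ended (adjusted p = 0.134 and adjusted p = 0.598) as SEs widened and degrees of freedom fell; over all alternatives the adjusted p lay between 0.00293 and 0.134 for Il7r and between 0.0235 and 0.598 for Rag2.

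Called genes were also placed in the gene order of assembly GRCm38.p6. Among the 26 genes 4 pairs lay within 50 tested genes of each other: Ehd3 with Gm6548, Gm6548 with Haao, Mnd1 with Rps3a1, and Nxpe5 with Zcwpw1. The pair of Mnd1 with Rps3a1 rests on the rising probe set being that of Rps3a1, and without it 3 pairs remain. Random sets of 26 genes held 1.42 pairs on average, and a share of 0.0547 of 10000 held 4 or more, so chance positions stay open. A segment of another strain that changes many genes around the targeted Ctcf locus is argued against: 7.04% of 199 genes around Ctcf, without Gm5914, had an unadjusted p under 0.05, against a median of 8% and an upper bound of 13% for the central 95% of 721 other windows. Gm5914, which adjoins Ctcf, fell, and Carmil2, the nearest tested gene on the other side, was also lower, at -0.40 (limma unadjusted p = 0.00668, adjusted p = 0.405). A shorter segment or an effect of the deletion on its neighbours stays open, and segments elsewhere were not tested.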
